A study of Mus musculus with 11 samples.

How the data were processed

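Reduced representation bisulfite sequencing (RRBS) was carried out on 11 libraries of ER-Hoxa9-Lys-GFP cells, a mouse C57BL/6 cell culture grown with or without estradiol, and the groups were taken from the labels. RRBS digests genomic DNA with a restriction enzyme, converts unmethylated cytosines with bisulfite and sequences the CpG-rich fragments. Per the labels' protocols, genomic DNA was purified from each sample, sequencing adapters were ligated, and the converted DNA was amplified by PCR. The same protocol text also names transposed nuclei, a step of another assay, and that part was not used here.

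The deposited tables list 1 line per CpG with the count of methylated reads and the count of all reads at that CpG, and they carry no header. A second deposited column holds a score of 0 to 1000, which equalled 1000 times the methylated share of the counts, to the nearest whole number, in 100.0% of lines of every library. Tests used the deposited counts, not the score. Per the submitters' processing notes, the genome build was mm9. The aligner, the methylation caller, read trimming and the treatment of PCR duplicates were not given in the sources used here. Listed positions on chromosome 7 reached 152520427, which lies 7196368 bp past the last gene of the GRCm38 gene table at hand. Coordinates are therefore given in mm9 as deposited (tile starts and ends are 1-based), none were converted, and no gene was assigned to a region. Lists of genes fixed beforehand were not tested, because a gene annotation of mm9 was not used here.

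The depth of a library is given as CpG-read observations, the sum of reads over all listed CpGs. It ranged from 8234933 to 46899896. A read that spans several CpGs is counted at each of them, and PCR reads without molecular identifiers are not independent molecules, so binomial intervals cover counting error only. The deepest CpG, at 98506660 on chromosome 2 in every library, took 2.151 to 2.795% of the observations of a library. Among CpGs listed in any library (1481716), 1190254 had at least 1 read in all 11 libraries, 391550 had at least 5, 74785 had at least 10 and 4988 had at least 20.

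For the planned comparisons, CpGs with at least 10 reads in all 11 libraries were summed into 500-bp tiles with at least 3 such CpGs. Here and in every later test only CpGs of chromosomes 1 to 19 and X were used. Of 6919 tiles, 70 with reads of 1 kind only were dropped and 6849 were tested. Each tile was fitted with a quasi-binomial logistic model of methylated against unmethylated reads with 1 mean per group, all 11 libraries in 1 fit, and compared by a two-sided deviance F test. The dispersion was moderated across tiles by limma's squeezeVar, rewritten in Python (largest relative difference from limma 7.3e-12), and was not allowed below 1. The Benjamini-Hochberg adjusted threshold was 0.05. The group kept in estradiol has 1 library, so its spread was assumed to be that of the other groups. These choices, and the alternatives listed for them, were made before the data were examined.

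A further version of each comparison, called the covered comparison here, was chosen after seeing the data. The planned test had called 0 tiles, and tiles of 5 reads per CpG, of 1 read per CpG with 30 observations per tile, and tiles at 5 to 95% methylation had been tried too. In the covered comparison the minimum of 10 reads applied only to the libraries of the groups compared, and only these entered the fit. The minimum of 3 CpGs, the test and the threshold were unchanged. For 120 h against 24 h this raised the tiles tested from 6849 to 71323. The covered comparison of 72 h with 24 h was not among the planned comparisons.

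The rule for named tiles, fixed before the data were examined, took up to 10 tiles higher and 10 lower with the largest difference in methylation among those past the threshold and with each library of 1 group above each library of the other, for 120 h against continuous estradiol, 120 h against 24 h, 72 h against continuous estradiol and the trend with hours, and the top 1 each way for other comparisons. Adjacent called tiles were merged for this naming only, and counts, medians and tests used single tiles unless regions are said to be merged. Because the planned test called 0 tiles, the rule was applied to the covered comparison.

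To place libraries between the 24 h and the 120 h level, the position of a library was its difference from the 24 h mean divided by the difference of the 120 h mean from the 24 h mean. The median over the called tiles and the ratio of summed differences were computed, with bootstrap 95% intervals over tiles (2000 draws), and tiles with under 10 observations in a library were left out for that library. The 24 h and 120 h libraries picked the tiles, so only the other 7 libraries are free of that selection. Correlations over 6 libraries used exact permutation tests, those over 10 or 11 libraries used 100000 permutations, and all were two-sided. Tiles with fewer than 10 listed CpGs were called sparse and those with 25 or more dense. CpGs and tiles with a mean over all libraries under 20% were called low, those above 80% high and the rest middle.

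The test was checked on simulated data drawn at the real depths, with 200 changed tiles. In the planned setting for 120 h against continuous estradiol it recovered 12.0% of tiles changed by 20 percentage points and 81.0% of those changed by 40 points, and 1 of 94 calls was false. For planned 120 h against 24 h these were 82.0% and 100.0%, with 3 of 185 calls false. In the covered comparison of 120 h with 24 h they were 45.0% and 96.0%, and 21 of 162 calls (13.0%) were false, above the nominal rate. None of these 21 reached 10 points, and they lay in deep tiles, with a median of 1712.2 observations per tile against 151.2 over all tiles. With 1 of its 4 libraries left out (24 h replicate 1), the covered comparison recovered 0.0% at either size, and against the lone estradiol library it also recovered 0.0%.

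Alternatives were other coverage minimums (5 and 20 reads), 1000-bp tiles, single CpGs, a difference of at least 10 points, an offset per library, leaving out CpGs above the 99.9th percentile of depth, no lower limit of the dispersion, a replicate block, each library left out in turn, and limma on log2((methylated + 1) / (unmethylated + 1)). The limma fit had no weights for depth. In tiles with reads of 1 kind only in a library, its value depends on depth alone. Its counts can therefore move with depth where the compared groups differ in it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.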

Results

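DNA methylation was measured by RRBS in ER-Hoxa9-Lys-GFP cells, mouse myeloid progenitors in which a fusion of Hoxa9 to the hormone-binding part of the estrogen receptor is active while estradiol is in the medium. Removal of estradiol switches the fusion off and lets the cells differentiate, and the Lys-GFP reporter marks lysozyme, a gene of maturing myeloid cells. The 11 libraries fall into 6 groups. A single library came from cells kept in estradiol. Pairs of libraries came from cells without estradiol for 120 h, and from cells without it for 24, 40, 56 or 72 h and then returned to it for 96, 80, 64 or 48 h. A longer absence thus always went with a shorter return, so effects of these times cannot be told apart. The labels do not say that the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. In the covered comparison of 120 h with 24 h that spread was largely borrowed across tiles (25.48 prior degrees of freedom), not measured at each tile.

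Depth differed between libraries. The library kept in estradiol had 12668839 CpG-read observations. The 24 h replicates had 16281112 and 46316547, the 40 h replicates 8234933 and 10317379, the 56 h replicates 9749600 and 8953231, the 72 h replicates 34706471 and 23871326, and the 120 h replicates 46899896 and 31240339. Methylation of the planned tiles was closely alike across libraries (Pearson's r across tiles 0.9931 to 0.9984). Replicates nevertheless differed by more than counting error, with a chi-square per degree of freedom of 1.59 to 2.17 in the 5 groups of 2.

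The comparison of 120 h without estradiol with 24 h of withdrawal and return set the longest absence against the shortest. A set of 28 regions of 500 bp fell, by a median of 23.5 percentage points (7.9 to 53.2), and 27 of them fell by 10 points or more. The largest fall was at chr1:178875001-178875500, from 96.2% ± 1.6 (SD, n = 2) at 24 h to 43.0% ± 0.5 at 120 h. The region chr10:87816501-87817000 fell from 76.8% ± 8.4 to 24.2% ± 1.1 (SD, n = 2), and chr17:79162501-79163000 from 85.0% ± 1.5 to 40.4% ± 8.6. In the library kept in estradiol these 3 regions were at 94.1% (Wilson 95% interval 73.0 to 99, 17 observations), 88.4% (75.5 to 94.9, 43 observations) and 94.6% (82.3 to 98.5, 37 observations).

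Other regions that fell included chr8:125804501-125805000, from 50.8% ± 1.1 to 9.7% ± 2.9 (SD, n = 2), and chr10:60664001-60664500, from 58.8% ± 6.6 to 18.3% ± 6.3. The region chr2:119122501-119123000 fell from 93.8% ± 2.2 to 53.4% ± 2.5, chr8:23501501-23502000 from 67.7% ± 0.3 to 30.3% ± 7.2, and chr2:72875501-72876000 from 62.7% ± 4.1 to 31.2% ± 9.8. Means at chr15:59538501-59539000 fell from 47.2% ± 2.4 to 15.7% ± 4.4, and those at chr19:58206501-58207000 from 58.2% ± 1.6 to 27.5% ± 2.2. Adjusted p-values of these 10 regions ranged from 3.96e-08 to 0.0065 in the quasi-binomial model with limma's moderation, at a mean of 24.3 to 61.3 reads per CpG in the compared libraries.

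**Figure D1:**
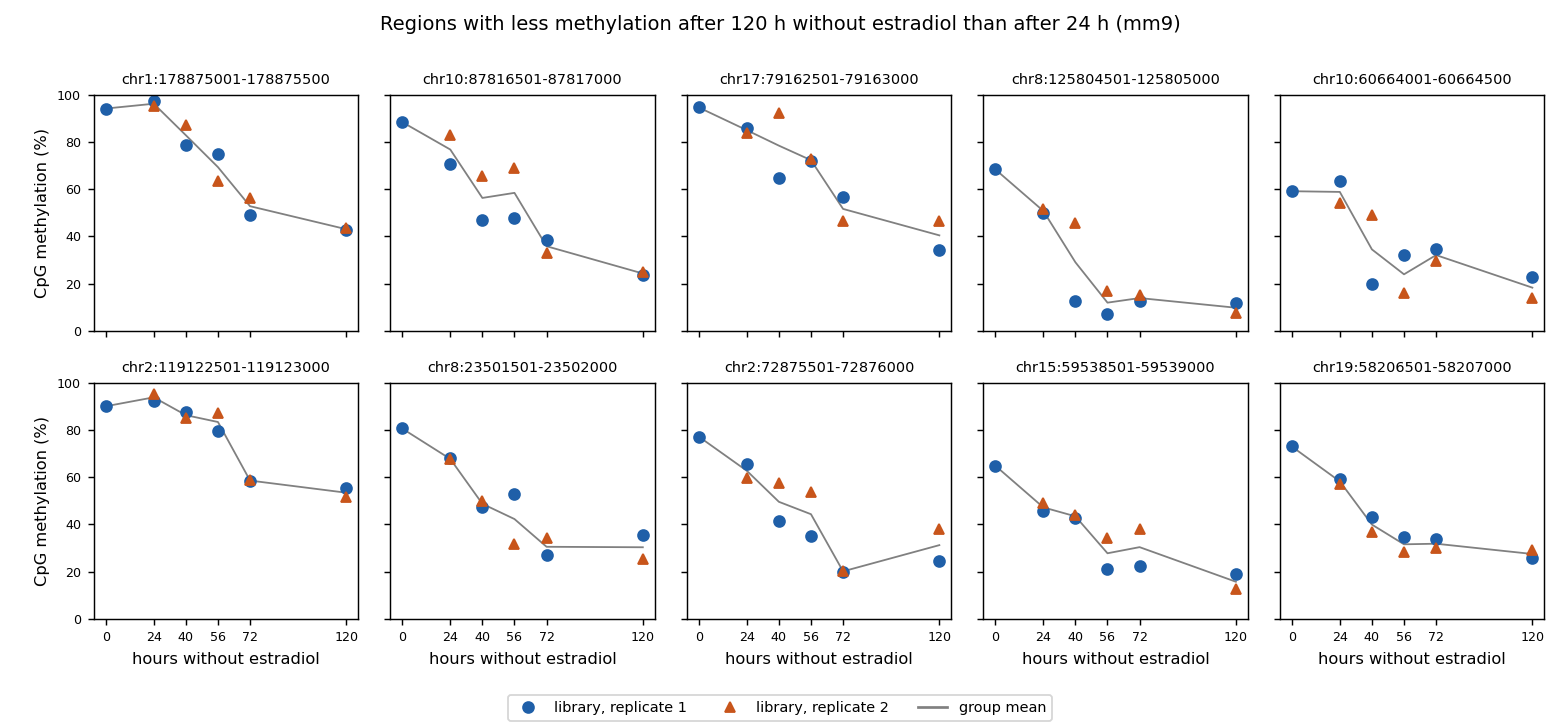
CpG methylation (%, y axis) against hours without estradiol (x axis) in each of the 11 libraries, for the 10 named regions lower at 120 h. Circles and triangles are replicates 1 and 2, and the line joins group means. The 24 h and 120 h libraries picked the regions, and at chr1:178875001-178875500 the means of the other groups were 94.1% at 0 h, 82.8% at 40 h, 69.3% at 56 h and 52.8% at 72 h.

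A further 28 tiles of 500 bp were more methylated at 120 h than at 24 h, by a median of 4.4 points (2.6 to 27.4), and 9 of them by 10 points or more. Of the 28, 10 lay at a single locus, chr17:39980001-39985500, where they rose by 2.6 to 5.4 points. Mean depth there was 901.7 to 2515.3 reads per CpG, against a median of 33.8 over the tiles tested. Why reads pile up at this locus was not tested, so these 10 may not be rises at an ordinary single-copy site. Adjacent tiles merged, there were 20 higher regions (median rise 5.7 points), while no 2 lower tiles were adjacent. Without the deepest CpGs, 10 higher and 23 lower tiles were called, and for single CpGs the calls were 9 higher and 51 lower. The region chr17:47899501-47900000 rose from 2.1% ± 1.1 at 24 h to 29.5% ± 4.0 at 120 h (SD, n = 2), and chr2:31656501-31657000 from 29.3% ± 5.6 to 56.6% ± 2.0. At chr2:31664001-31664500 methylation rose from 0.9% ± 0.5 to 11.9% ± 0.4, and at chr2:34476001-34476500 from 3.4% ± 1.2 to 25.9% ± 7.4. The region chr12:93017501-93018000 rose from 23.8% ± 0.8 to 46.4% ± 0.6, and was at 42.2% (Wilson 95% interval 33.4 to 51.6, 109 observations) in the library kept in estradiol. Methylation also rose at chrX:20002501-20003000 (45.8% ± 5.6 to 62.4% ± 2.9), chr1:39451001-39451500 (5.8% ± 3.0 to 21% ± 3.6), chr5:140199501-140200000 (0.8% ± 1.1 to 14.9% ± 1.8), chr6:116600501-116601000 (0.3% ± 0.5 to 12.5% ± 5.8) and chr9:56071501-56072000 (22.3% ± 1.7 to 28.3% ± 0.5). Adjusted p-values of the 10 named higher regions ranged from 1.15e-05 to 0.0101 in the same model, and the call at chr9:56071501-56072000 was lost (adjusted p = 0.936) without the deepest CpGs.

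The 2 directions differed in how well replicates of other groups matched. In the 40, 56 and 72 h groups, which took no part in the selection, the chi-square between replicates was 95.82 per pair at the higher tiles, 2.05 at the lower tiles, 1.42 over all tiles tested and 7.08 over the deepest 1% of tiles (716). It was 138.55 at the 19 higher tiles that moved by under 10 points, whose median depth was 1585.1 reads per CpG, and 3.79 at the 9 that moved by more. Of the higher tiles, 18 lay in that deepest 1%, against 1 of the lower tiles.

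These 56 calls came from the covered comparison, which tested 71323 tiles. In the planned fit of 6849 tiles the same comparison called 0 (374 at an unadjusted p under 0.05), and limma called 0 in both versions (390 and 3253 at an unadjusted p under 0.05). Leaving out any 1 of the 4 libraries also gave 0 calls. Simulated without 24 h replicate 1, the only such case, on tiles covered in the libraries left, none of the changes were recovered. For the full comparison the simulation called 162 tiles, 21 of them (13%) falsely, and none of these 21 by 10 points or more. That share depends on the 200 changed tiles put in and on a fixed noise setting, so it does not carry over to the 56 calls. Of the 56 calls, 36 differed by 10 points or more. An unadjusted p under 0.05 was found in 5.46% of tiles in the planned fit and in 5.17% (3689) in the covered comparison. Over all comparisons by the quasi-binomial test this share ran from 0.01 to 5.46%. With no difference at any tile about 5% would be found, so these counts are no sign of further changes.

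Regions that fell were mostly CpG-sparse. Of the 28, 25 (89.3%) were sparse, against 64.0% of all tiles tested (odds ratio 4.69, Fisher's exact test, two-sided, adjusted p = 0.0116 over 24 tests)). Among the 53170 tiles at 20% methylation or more in the library kept in estradiol, 74.4% were sparse, and the odds ratio was 2.86 (Fisher's exact test, two-sided, p = 0.0829). Of the 21 tiles lower at 72 h than at 24 h, 15 were sparse (71.4% against 63.0%, odds ratio 1.47, Fisher's exact adjusted p = 0.575).

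Libraries that took no part in choosing the regions were then placed between the 24 h level (0) and the 120 h level (1). At the 28 lower regions, the ratio of summed differences placed the library kept in estradiol at -0.19 (bootstrap 95% interval -0.29 to -0.08), above the 24 h cells in methylation. The 40 h replicates lay at 0.51 and 0.22, the 56 h replicates at 0.7 and 0.7, and the 72 h replicates at 0.84 (0.74 to 0.93) and 0.82 (0.7 to 0.94). Mean methylation over these regions was 78.9% in continuous estradiol, 74.0% at 24 h, 63.8% at 40 h, 55.5% at 56 h, 52.0% at 72 h and 47.5% at 120 h. The 72 h libraries had spent 48 h back in estradiol. At the 15 tiles lower at a minimum of 20 reads per CpG, the library kept in estradiol lay at 0.17 (-0.14 to 0.55) and the 56 h replicates at 0.6 (0.26 to 0.98) and 0.75 (0.47 to 1.02).

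Over the 6 libraries of 40, 56 and 72 h, the median position at the lower regions rose with hours (Pearson's r = 0.86, Spearman's rho = 0.96, each with an exact permutation p = 0.0222, the smallest this design gives). Adjusted over a family of 6 relations the p was 0.0666, so the relation failed the threshold of 0.05. The 40 h and 72 h libraries are equally far from the median time, and r was 0.96 without the 40 h pair and 0.82 without the 72 h pair (4 libraries left). At the higher tiles r for the median position was 0.17 (exact permutation p = 0.756, rho 0.24, exact permutation p = 0.711). For the ratio of summed differences r was 0.36 (exact permutation p = 0.444). By that ratio replicates 1 and 2 lay apart, at -0.02 and 0.52 for 40 h, 0.25 and 0.89 for 56 h, and 0.22 and 0.88 for 72 h. The 2 splits that mix 24 h and 120 h libraries called 0 tiles, so their axes were picked from the 56 tiles with the smallest p. At lower tiles this ratio, in the other libraries, ran from 0.45 to 0.88. That range arose with no contrast of 24 h with 120 h, and it holds the 56 h and 72 h positions above and 0.51 of 40 h replicate 1. It does not hold -0.19 in continuous estradiol or 0.22 of 40 h replicate 2. Of these splits, 1 set the 2 deeper libraries against the other 2, so depth may enter it besides selection. On these 2 axes the r with hours was -0.17 and -0.11 for the median position (exact permutation p = 0.844 and 0.867) and -0.47 and 0.46 for the ratio (exact permutation p = 0.356 and 0.422).

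**Figure D2:**
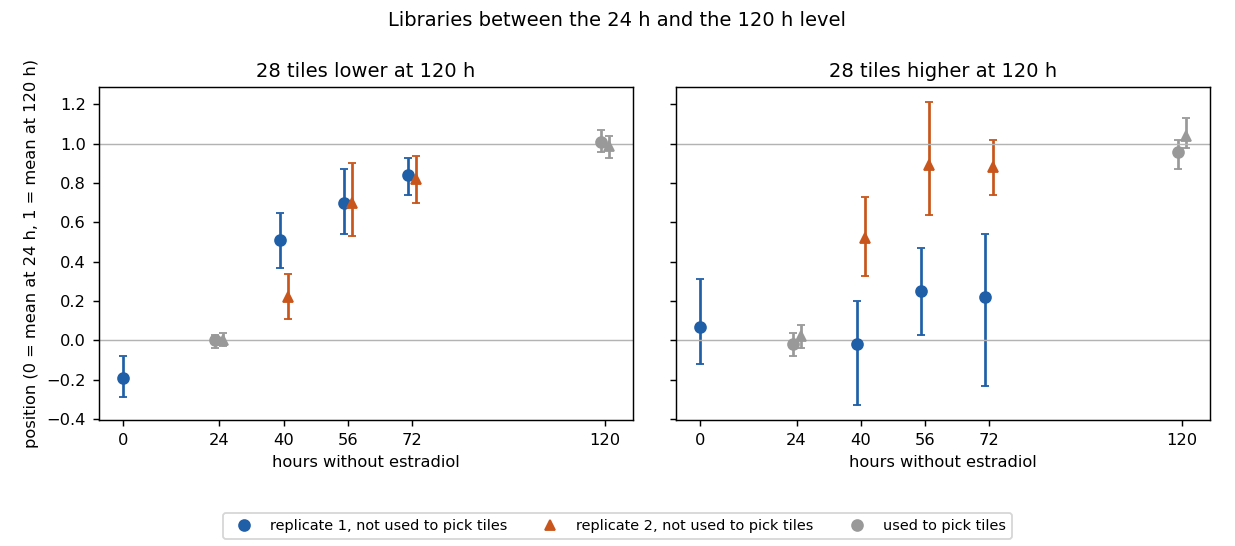
Position of each library (y axis, 0 is the 24 h mean and 1 the 120 h mean) against hours without estradiol (x axis), for the 28 lower and 28 higher tiles; bars are bootstrap 95% intervals over tiles. Grey points picked the tiles. Coloured points did not, and at the lower tiles they run from -0.19 in continuous estradiol to 0.84 and 0.82 at 72 h.

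Cells withdrawn for 72 h and returned were compared with those withdrawn for 24 h and returned, a comparison added after seeing the data. A set of 21 regions was lower after 72 h, by a median of 27.5 points, and 6 were higher, by a median of 20.1 points. The region chr1:178875001-178875500 fell by 43.4 points, to 52.8% ± 5.0 (SD, n = 2). The region chr2:34476001-34476500 rose by 29.7 points, to 33.1% ± 5.3. Both regions were also called for 120 h against 24 h, a comparison that shares the 24 h libraries, so the calls are not independent of it. The covered comparison tested 67407 tiles (3372, or 5.0%, at an unadjusted p under 0.05, the share that no difference would give). Of these tiles limma called 0 (3076 at an unadjusted p under 0.05). A refit at a minimum of 20 reads per CpG called 1 of 15413 tiles.

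A contrast that shares no library with the selection set 72 h and return against continuous estradiol. At the regions lower at 120 h than at 24 h, methylation at 72 h was below that in continuous estradiol in 26 of 26 regions with at least 20 observations on each side (Wilson 95% interval 87.1 to 100%), with a mean difference of -25.28 points. Among tiles with an unadjusted p over 0.5 between 24 h and 120 h, 55.6% of those with a lower 120 h mean did so. At the higher tiles 16 of 27 moved the same way (59.3%, Wilson 95% interval 40.7 to 75.5), against 44.2% of tiles with a higher 120 h mean and a p over 0.5. Both intervals cover tiles, not libraries. All tiles share the lone estradiol library and the 72 h pair, so they are not independent trials. The tiles with a p over 0.5 were not matched to the called tiles in methylation. By the mean of the libraries that picked the tiles, most called tiles were of middle methylation, while most tiles tested were high.

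Methylation after 120 h without estradiol was also set against continuous estradiol, the full contrast of the design. At the 10 named regions that fell, picked on the 24 h and 120 h libraries, the library kept in estradiol was at 59.1 to 94.6% and the 120 h means at 9.7 to 53.4%. Of the tiles tested, 97.37% differed by less than 10 points. The quasi-binomial test called 0 of 6849 tiles (229 at an unadjusted p under 0.05) and limma called 0 (877). The covered comparison, chosen after seeing the data, called 0 of 51370 tiles (789 at an unadjusted p under 0.05), and 35 (18 higher, 17 lower) of the 18997 at 5 to 95% methylation. In the planned fit the 95% half-width at tiles of middle methylation was 14.7 points, with 1 estradiol library.

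Cells returned to estradiol after 24, 40, 56 or 72 h were compared with cells never withdrawn. At chr2:31656501-31657000, picked on the 24 h and 120 h libraries, methylation was 18.5% in continuous estradiol (Wilson 95% interval 10.9 to 29.6, 65 observations), 29.3% ± 5.6 at 24 h, 41.8% ± 0.5 at 40 h, 47.3% ± 5.8 at 56 h and 51.9% ± 1.8 at 72 h (SD, n = 2). At chr19:58206501-58207000, picked likewise, it was 73.0% in continuous estradiol (61.9 to 81.8, 74 observations), 39.9% ± 4.7 at 40 h and 31.8% ± 2.7 at 72 h. The quasi-binomial test called 0 tiles at 24, 40, 56 and 72 h (213, 203, 179 and 232 at an unadjusted p under 0.05), and limma called 0 in each (628, 307, 306 and 753). In the covered versions it called 0 of 42623, 9259, 10817 and 48904 tiles (278, 1, 2 and 353 at an unadjusted p under 0.05).

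Against 120 h without estradiol, cells returned after 40, 56 or 72 h showed no tile past the threshold. The region chr2:72875501-72876000, picked on the 24 h and 120 h libraries, was at 20.1% ± 0.4 at 72 h and 31.2% ± 9.8 at 120 h (SD, n = 2). The quasi-binomial test called 0 tiles at 40, 56 and 72 h (231, 218 and 335 at an unadjusted p under 0.05), limma called 0 (1648, 1561 and 342), and the covered versions called 0 of 13097, 15096 and 92383 tiles (394, 448 and 3962). The 40 and 56 h libraries had a median of 60 to 71 observations per planned tile, against 325 and 222 at 120 h. The limma fit was not weighted for depth. Its 1648 and 1561 may therefore reflect depth and cannot be read as differences in methylation. In the simulation at 72 h depths 16.0% of 20-point changes and 77.0% of 40-point changes were recovered.

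Whether methylation after return depends on the hours without estradiol was tested over the 8 returned libraries. The slope passed the threshold in 0 of 6849 tiles (270 at an unadjusted p under 0.05; limma 0 and 160), and in 12 (11 lower with hours, 1 higher) when the dispersion had no lower limit.

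Mean methylation of highly methylated CpGs (31935 CpGs with a mean above 80%) fell slightly with hours without estradiol. It was 96.33% in continuous estradiol, 96.12% ± 0.02 at 24 h, 96.12% ± 0.02 at 40 h, 95.89% ± 0.07 at 56 h, 95.84% ± 0.06 at 72 h and 95.86% ± 0.11 at 120 h (SD, n = 2 except the first). Over 11 libraries Pearson's r was -0.79 (permutation p = 0.00299, adjusted 0.0405 over 14 relations) and Spearman's rho -0.82 (permutation p = 0.00309, adjusted 0.0108). Without the 120 h pair, farthest from the median time, r was -0.95. Over the 10 withdrawn libraries r was -0.71 (permutation p = 0.02, adjusted 0.0871) and rho -0.76 (permutation p = 0.0149, adjusted 0.0348). CpGs of sparse tiles (38207) moved likewise over 11 libraries (r = -0.76, permutation p = 0.00579, adjusted 0.0405, and rho = -0.84, permutation p = 0.00203, adjusted 0.0108), with r = -0.88 without the 120 h pair. Over the 10 withdrawn libraries their r was -0.67 (permutation p = 0.0334, adjusted 0.0935) and rho -0.79 (permutation p = 0.0104, adjusted 0.0291).

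**Figure D3:**
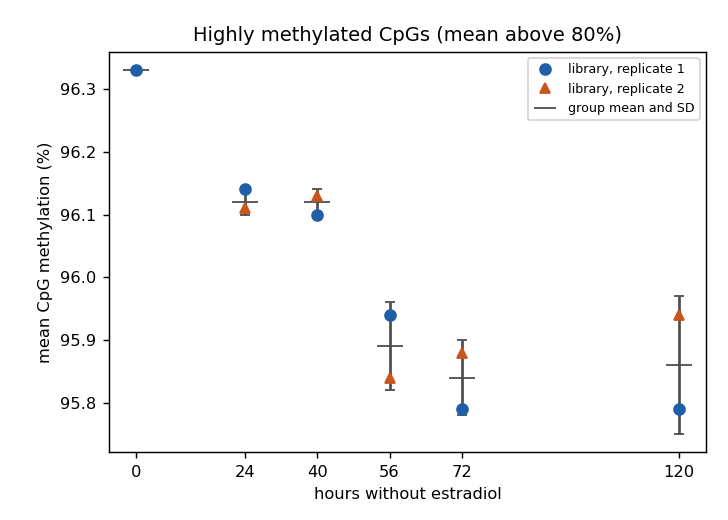
Mean methylation of 31935 highly methylated CpGs (%, y axis, from below 96% and not from 0) against hours without estradiol (x axis). Points are libraries and horizontal marks are group means with SD, from 96.33% in continuous estradiol to 95.86% at 120 h.

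Over all 74769 CpGs with at least 10 reads in every library on the autosomes and X, the group means ran from 47.14% in continuous estradiol to 46.85% ± 0.03 at 120 h (SD, n = 2). The rank correlation with hours passed the threshold (rho = -0.9, permutation p = 0.00049, adjusted 0.00686), while Pearson's r did not after adjustment (r = -0.66, permutation p = 0.0249, adjusted 0.0871), was -0.81 without the 120 h pair, -0.51 without the estradiol library and reached 0.08 at a minimum of 20 reads. CpGs of low, middle, intermediate-density or dense classes showed no relation past the threshold in either measure.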

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

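In this part, the split count, the depth test, and the interval and second noise of the mixing residual for the lower regions, the replicate-spread test of the higher tiles, the over-conversion test and the comparison of 72 h with 24 h were chosen after the results were seen. A difference in the effect of withdrawal and return between 2 durations is what marked this result: 27 regions were called between cells returned after 72 h and after 24 h, each compared by a test of the difference itself (adjusted p in the quasi-binomial model). The calls depend on the test, as limma called 0 (3076 at an unadjusted p under 0.05), and on coverage, as a refit at 20 reads per CpG called 1. They share both 24 h libraries with the comparison of 120 h with 24 h, and several regions were called in both, so they are not a separate result. The 72 h replicates also differed most, with a chi-square per degree of freedom of 2.17 against 1.59 to 1.63 in the other groups.

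The 28 regions lower at 120 h than at 24 h are the pattern a reader would most want to follow. Depth alone is weakly argued against by 24 h replicate 2 and 120 h replicate 1, of almost equal depth (46316547 and 46899896 observations). At 244 tiles picked on the other 2 libraries alone by a fall of 20 points or more, they differed by a mean of 3.41 points (bootstrap 95% interval 1.97 to 4.97), against 0.18 over all tiles. Of these 244 tiles 143 fell, and the interval covers tiles, not libraries. At the 28 regions they differed by 26.79 points (22.12 to 31.6), which is no evidence here, since they helped to pick these regions. The 4 libraries can be split in only 3 ways, too few for a share under 0.05, and the real split, which called 56 tiles against 0 for the highest other, was the largest, 1 of 3. A mixture with 1 share of cells at the 120 h state per library (21.2 to 86.7%) left a residual of 1.68 times the replicate noise (chi-square p = 1.58e-07 over 161 degrees of freedom). This met the rule set before against such a mixture, a residual above 1.5 with a bound on p. Checks added afterwards were less clear. The bootstrap 95% interval of the residual over tiles, 1.22 to 2.04, includes 1.5. Over the replicate noise of these tiles the residual was 1.33 (chi-square p = 0.0036), under 1.5. In libraries that took no part in the selection, methylation at 72 h was below that in continuous estradiol at 26 of 26 of these regions (mean -25.28 points). This contrast rests on the lone estradiol library and a single duration. Its regions share the same libraries, so they are not independent trials. Hours without estradiol cannot be told apart from hours of return. A difference still present after 48 h of return may hold, with its dependence on hours and the mixture still open.

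The 28 tiles higher at 120 h, 10 of them at chr17:39980001-39985500, may in large part reflect replicate spread that the fit of 4 libraries estimated as too small. The chi-square between replicates of the 40, 56 and 72 h groups was 95.82 there. By the ratio of summed differences, replicate 2 lay above replicate 1 in each of these groups (0.52 against -0.02, 0.89 against 0.25 and 0.88 against 0.22). At the 9 tiles that moved by 10 points or more the chi-square was 3.79, far under the 138.55 of the other 19 but above the 1.42 over all tiles. This value also passed the bound chosen for this test, so replicate spread may account for these 9 too. A rise with hours remains open at some of these 9, such as chr2:31656501-31657000, but chr12:93017501-93018000 (42.2% in continuous estradiol, 22.8% at 72 h and 46.4% at 120 h) and chrX:20002501-20003000 (54.3, 53.0 and 62.4%) did not follow the hours.

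The small fall of highly methylated CpGs with hours is not accounted for by depth alone, since r was -0.76 (permutation p = 0.00671) after log depth was taken out. Over-conversion by bisulfite would lower sparse and dense CpGs alike, and the fall per 100 h was 0.413 points at sparse and 0.061 points at dense highly methylated CpGs (interval of the difference 0.031 to 0.929). The correlation of the sparse minus dense difference with hours was -0.59 (permutation p = 0.055), so this stays open, with only 944 dense CpGs behind it. An effect of estradiol withdrawal on methylation across the genome could be another source and was not separated from it.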

How the results depend on the processing

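The covered comparisons, tiles of 30 observations, tiles at 5 to 95% and the alternatives of the covered comparisons, the positions (but for tiles covered in every library) and the highly methylated CpGs were chosen after seeing the data. Of 173 alternatives to the planned comparisons, 161 also gave 0 calls, among them all 34 that left out 1 library, where the lone sample of a group is assumed to vary like the other groups. For 120 h against 24 h, calls came to 3 at 5 reads, 4 in 1000-bp tiles, 36 (30 higher, 6 lower) with only the 4 libraries in the fit, 11 in tiles of 30 observations, 10 at 5 reads and 5 to 95%, and 56 in the covered comparison. The trend with hours gave 12 with no lower limit of the dispersion, 2 in tiles of 30 observations, 1 at 5 to 95%, 12 at 5 reads and 5 to 95%, and 1 in the covered version. For 120 h against continuous estradiol, 5 reads and 5 to 95% gave 1 call, and the covered version gave 35 (18 higher, 17 lower) at 5 to 95% against 0 otherwise. The cause of these changes was not tested.

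In the covered comparison of 120 h with 24 h, 36 calls were at least 10 points, 33 (10 higher, 23 lower) were left without the deepest CpGs, and limma and each library left out gave 0 (0 to 0). The split moved to 33 higher and 15 lower at 20 reads and to 9 and 51 for single CpGs. For 72 h against 24 h, calls were 1 at 20 reads, 76 for single CpGs, 16 at 5 to 95%, and 0 by limma and with each library left out (0 to 0). For 120 h against 24 h without 24 h replicate 1, the only such case simulated, none of the changes were recovered. The simulation used 111230 tiles covered in the libraries left, against 71031 in the real fit, so it only approximates that setting. A zero from such a fit therefore says nothing about stability. An alternative that left a named region untested, for example by too few covered CpGs, was not counted for it, here or among the 74 below. Of 162 alternatives run tile by tile for the named regions 0 reversed. Where a library was left out this was fixed in advance, since naming required the libraries of the groups to lie apart. Of the 74 alternatives that kept all libraries, 73 kept the call, and the call was lost in those that left out a library. None of these regions passed under limma, which kept all libraries of the comparison.

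With all CpGs, r with hours was 0.08 at 20 reads, reversed, -0.21 for pooled reads and -0.74 to -0.51 with each library left out. For highly methylated CpGs it kept its direction in the alternatives run, from -0.89 to -0.71, with an unadjusted permutation p under 0.05, but without the estradiol library the adjusted p was 0.0871. The position trend was 0.72 at 20 reads, 0.83 for regions picked on replicates 1, 0.66 for 6 tiles covered in every library picked the same way, and 0.83 to 0.98 with each library left out (exact permutation p = 0.0222 without a 24 h or 120 h library, and 0.0667 without one of 40, 56 or 72 h, the smallest that 5 libraries gave). Picking those tiles on replicates 2 left 0 tiles and no value. At the higher tiles it turned to -0.06 at 5 reads. Over 44309 tiles replicate numbers did not pair the samples (correlations of replicate differences between groups -0.002 to 0.024), though at the 28 higher tiles replicate 2 lay above replicate 1 at 40, 56 and 72 h. The replicate block gave 0 calls in both covered comparisons with calls (66 and 34 at an unadjusted p under 0.05), so no named region passed there either, r = -0.54 for all CpGs and -0.72 for highly methylated CpGs.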

Other observations

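Some regions moved after 72 h of withdrawal and return and are described here only because their values were seen. At chr4:8781001-8781500 methylation was 100% in continuous estradiol (Wilson 95% interval 91.2 to 100, 40 observations), 95.6% ± 1.2 at 24 h, 96.3% ± 2.6 at 40 h, 77.5% ± 5.1 at 56 h, 65.4% ± 4.4 at 72 h and 75.0% ± 1.4 at 120 h (SD, n = 2). At chr8:47223501-47224000 it was 67.5% ± 1.2 at 24 h, 57.9% ± 6.5 at 40 h, 25.4% ± 3.3 at 56 h, 34.4% ± 0.5 at 72 h and 43.9% ± 6.6 at 120 h. At chr10:81027001-81027500 it was 16.4% ± 1.2 at 24 h, 39.7% ± 1.2 at 72 h and 31.3% ± 10.0 at 120 h, and at chr9:44076001-44076500 29.9% ± 0.9, 46.7% ± 1.8 and 35.6% ± 0.7.

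A pair of regions on chromosome 2, chr2:31656501-31657000 and chr2:31664001-31664500, lie close together and both were more methylated at 120 h than at 24 h. The second was at 0.8% in continuous estradiol, 1.1% ± 0.2 at 40 h, 4.6% ± 2.4 at 56 h, 8.3% ± 4.2 at 72 h and 11.9% ± 0.4 at 120 h (SD, n = 2).

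The libraries listed 728 to 850 CpGs on chromosome Y, with 0.0417 to 0.0479% of observations and a methylation of 89.1 to 91.0%.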
